A study of Arabidopsis thaliana with 6 samples.

How the data were processed

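Arabidopsis thaliana seedlings, labelled as whole plants, were profiled by RNA sequencing in 6 libraries, 3 from the Col-0 wild type (WT) and 3 from the nid1 knockout mutant. Per the labels' protocols, plants were 9 days old and grew at 23 °C and 60% relative humidity with 16 h of light and 8 h of dark. They were grown on medium with 20 mM nitrate, moved to nitrate-deficient conditions and then given 0.05 mM nitrate for 6 h. Libraries were made with a stranded poly(A) kit and read as 101 bp pairs, per the labels' protocols. Groups and replicate numbers were taken from the sample titles.

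The deposited values are FPKM, fragments scaled by transcript length and by library, with 1 value per gene and library. The unit was read from the identifier column, which bears Cuffdiff's column name per the file headers, from the submitters' processing notes and from the values. The submitters' processing notes name bcl2fastq 2.20, Bowtie without a version, TopHat2 2.0.13 and Cuffdiff 2.2.1, without roles or order. The series' design text names another sequencer model and also a BWA route followed by ANOVA, and it speaks of isoforms, while the deposited rows are genes. Which strand setting was used, how fragments from near-identical genes were divided and how libraries were scaled are not given in the sources used here. The authors' Cuffdiff values estimate how fragments divide between overlapping transcripts, so overlapping, antisense and near-identical genes are uncertain. The genome build is not given in the sources used here. Of the 38150 identifiers, 37932 matched locus tags of the RefSeq annotation of TAIR10.1. The other 218 name mitochondrial positions, and all 218 positions equalled annotated features of that annotation. Coordinates are therefore given on TAIR10.1, 1-based, from the RefSeq annotation.

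No fragment counts were used here, so depth is known only roughly. In genes with 1 transcript longer than 1500 bp, low FPKM values multiplied by the transcript length less an assumed fragment length of 200 bp piled up near the worth of 1 fragment. The most frequent such value gave an approximate depth relative to WT replicate 1. These steps were smeared and whole counts were not recovered. No interval from counting error can be given. Exact zeros can be failed estimates, since 48 genes were listed at 0 in at least 1 library and at 10 FPKM or more in another.

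Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with genotype as the only term. Genes at 1 FPKM or more in at least 3 of the 6 libraries were kept, which left 20533. P-values were adjusted by the Benjamini-Hochberg method over these genes, and a gene is called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes; ratios of mean FPKM are given beside them where stated. A set of 25 gene lists from textbook knowledge, the single-gene test, the filter, the alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists with tested members. The same test with an estimated correlation, and the rotation test fry, were alternatives. Members are also counted after adjustment over the list alone.

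The naming rule took, among called genes whose 3 values in one genotype all lay above those of the other, the 12 with the largest changes in each direction with a mean of at least 5 FPKM in the higher genotype. It also took up to 4 called members of each list by smallest p, and NRT2.1, NRT1.1, NIA1, NIA2 and NIR1 whatever their result. It would have taken a gene called NID1, but no gene of the reference annotation bears that name. The first part named 13 genes. The other 5 called genes, and list members that were not called over all genes, were chosen after their values were seen.

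The test was checked on data simulated from the same 20533 genes, with 50 genes changed at each of several sizes in the nid1 against WT comparison. At a log2 change of 0.5 it recovered 0% of the changed genes, at 1 it recovered 72%, at 2 it recovered 100% and at 3 it recovered 98%, with 12 calls among unchanged genes. A simulated list shifted by 0.5 was called and 0 of 20 unshifted lists were. Genes were simulated independently of one another, while the estimated correlation was 0.80 in the photosynthesis list. The check therefore does not cover lists whose members vary together. The Benjamini-Hochberg threshold also eases as more genes change. At a log2 change of 2 alone 50 simulated genes were recovered, while 18 genes were called in the real data. The recovered shares can therefore overstate recovery in the real data.

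The alternatives were a replicate block, leaving out each replicate with the tested genes held fixed, pseudocounts of 0.1 and 0.5, a filter at 0.1 FPKM, no filter beyond a value above 0, rescaling of libraries by median ratios, and limma without the trend or with robust variance moderation (statmod 1.5.0). The other splits of the 6 libraries into groups of 3 were also fitted. Figures were drawn with matplotlib in Python.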

Results

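The series compared 9-day-old seedlings of wild-type Arabidopsis (accession Col-0), labelled as whole plants, with the nid1 knockout mutant after 6 h at 0.05 mM nitrate, a low supply. There were 3 libraries per genotype, and each held FPKM values for 38150 genes. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. FPKM summed to 730062, 964273 and 758728 in WT replicates 1, 2 and 3, and to 797123, 804310 and 740626 in nid1 replicates 1, 2 and 3. The approximate depth relative to WT replicate 1 was 0.786 and 0.932 in WT replicates 2 and 3. It was 0.645, 0.682 and 0.824 in nid1 replicates 1, 2 and 3, so the nid1 libraries were on average the shallower ones. Pearson correlations of log2(FPKM + 1) across genes lay between 0.970 and 0.990 for all pairs of libraries. WT replicate 2 stood apart on the first principal component, which held 38.3% of the variance. The sources used here do not give the locus that the nid1 mutation removes, so its transcript was not checked.

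Few genes differed between the genotypes beyond the replicate spread, and several of them were nearly silent in WT and expressed in nid1. On the log2(FPKM + 1) scale the long non-coding RNA AT1G07887 rose most, from 1.00 ± 0.0993 FPKM in WT to 73.3 ± 6.61 FPKM in nid1 (SD, n = 3 each), but its exon lies wholly within those of a neighbour and its value is uncertain. A cyclophilin-like peptidyl-prolyl isomerase gene, AT3G55920, rose from 1.07 ± 0.266 to 16.0 ± 0.979 FPKM. AT3G05170, of the phosphoglycerate mutase family, rose from 0.463 ± 0.0616 to 7.79 ± 0.699 FPKM. In the other direction the long non-coding RNA AT3G05945 fell from 27.3 ± 7.09 to 2.86 ± 0.726 FPKM, and SADHU3-2, a copy of a retroelement family, fell from 42.7 ± 12.4 to 5.42 ± 0.932 FPKM. The limma log2 fold changes were 5.21 for AT1G07887 (SE 0.120, adjusted p = 2.56e-06) and 3.05 for AT3G55920 (SE 0.136, adjusted p = 0.000229). That of AT3G05170, at 1466483 to 1468400 on chromosome 3, was 2.58 (SE 0.126, adjusted p = 0.000295). For AT3G05945, at 11510090 to 11510510 on chromosome 3, and SADHU3-2 (AT3G42658), at 14749400 to 14750294 on chromosome 3, limma gave -2.86 and -2.74 (adjusted p = 0.00382 for both). Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes.

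In all, limma called 18 of 20533 genes at an adjusted p under 0.05, 13 higher and 5 lower in nid1, and each call was at least 2-fold. The count was 9 without WT replicate 1, 25 without WT replicate 2 and 8 without WT replicate 3. It was 35 without nid1 replicate 1, 8 without nid1 replicate 2 and 10 without nid1 replicate 3. At an unadjusted p under 0.05 there were 1275 genes, where chance gives about 1027. The groups did not overlap in 10.3% of tested genes, and chance gives 10% for 3 against 3. The genes called in all of 14 other settings of the fit numbered 7, namely AT1G07887, AT3G55920, AT3G55910, AT3G05170, AT3G05945, SADHU3-2 and AT4G39364. The other 11 all lost their call without nid1 replicate 2. Of the 18, 8 stayed called without WT replicate 1, 14 without WT replicate 2, 8 without WT replicate 3, 15 without nid1 replicate 1 and 10 without nid1 replicate 3.

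**Figure D1:**
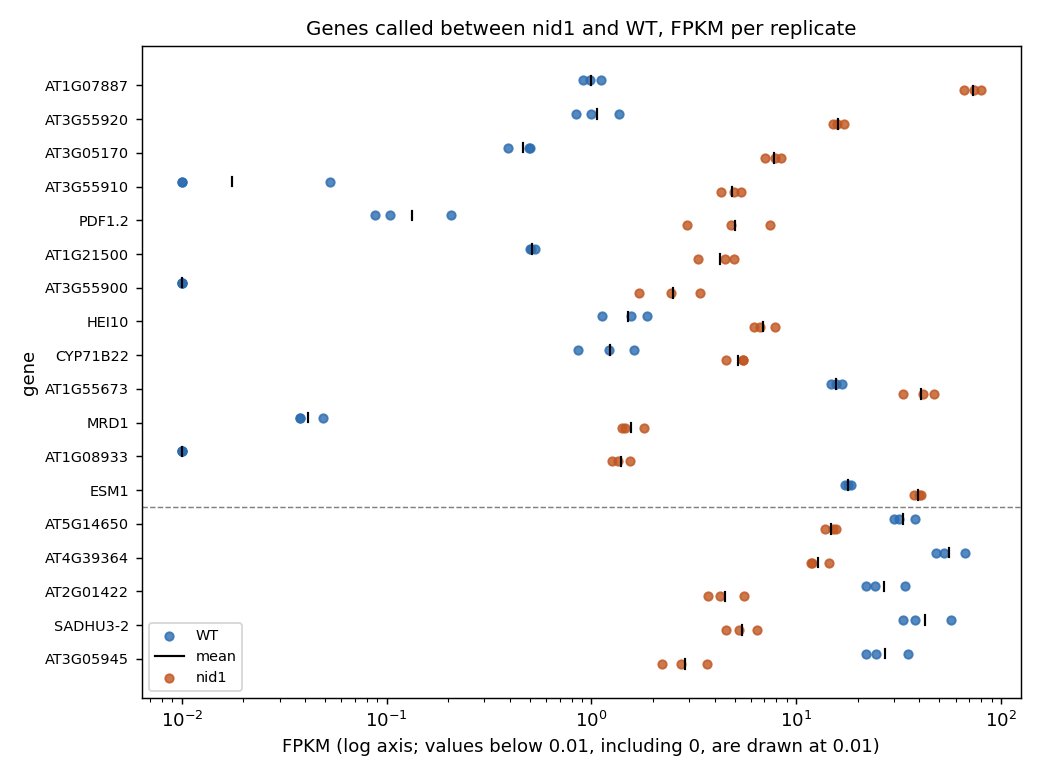
FPKM of the 18 called genes (horizontal log axis) in each replicate of WT (blue) and nid1 (orange), with black ticks at the group means (n = 3); values below 0.01, including 0, are drawn at 0.01. The 13 genes above the dashed line are higher in nid1 and the 5 below it are lower, with no overlap between the genotypes.

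Of the called genes, 6 formed 2 groups of neighbours. On chromosome 1, MRD1 (AT1G53480, 19963047 to 19964712, minus strand), AT1G07887 (19963067 to 19964105, plus strand) and HEI10 (AT1G53490, 19963267 to 19966952, plus strand) overlap. HEI10, which encodes a RING protein known from meiotic crossover formation, rose from 1.52 ± 0.370 to 6.92 ± 0.879 FPKM (log2 fold change 1.66, SE 0.157, limma adjusted p = 0.0133). MRD1 rose from 0.0414 ± 0.00629 to 1.56 ± 0.214 FPKM (log2 fold change 1.29, SE 0.133, limma adjusted p = 0.0193). All 1039 exonic bases of AT1G07887 lie within exons of MRD1 on the other strand, and 839 lie within exons of HEI10. HEI10 has 2252 exonic bases, of which 922 lie within exons of MRD1. Fragments from the shared bases were divided by the authors' estimate, so the values of all 3 genes are uncertain, and that of AT1G07887 rests wholly on shared bases.

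On chromosome 3, AT3G55900 (an F-box gene, 20742166 to 20742653, minus strand), AT3G55910 (an ARF GTPase-activating protein gene, 20742676 to 20743479, plus strand) and AT3G55920 (20743443 to 20745153, minus strand) lie side by side. AT3G55900 was listed at 0 in all 3 WT libraries and at 2.434, 3.374 and 1.703 FPKM in nid1 replicates 1, 2 and 3. AT3G55910 was listed at 0, 0 and 0.0528 FPKM in WT and at 4.30, 5.38 and 4.97 FPKM in nid1. AT3G55910 and AT3G55920 share 37 exonic bases, on opposite strands, and AT3G55900 shares none with either. The neighbour AT3G55890, which overlaps AT3G55900 by 276 exonic bases, measured 15.2 ± 3.37 FPKM in WT and 15.2 ± 2.61 FPKM in nid1 and was not called (limma adjusted p = 1.00). The value of AT3G55900 is uncertain for this overlap.

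**Figure D2:**
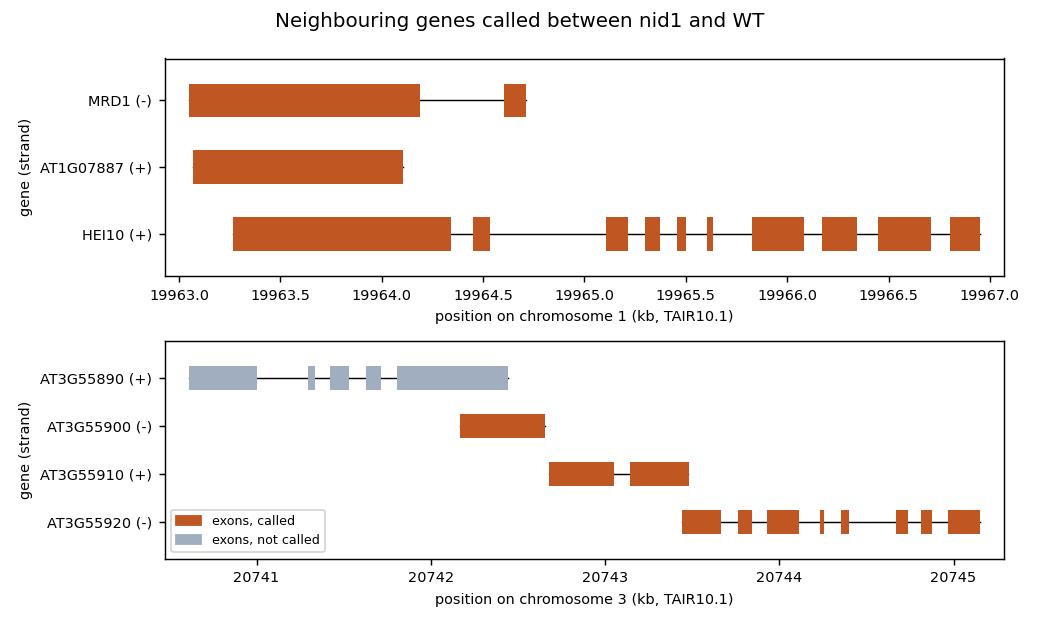
Exons (boxes) of the neighbouring called genes (orange) and of the uncalled AT3G55890 (grey) on TAIR10.1, with position in kb on the horizontal axis and 1 gene per line with its strand. The 3 genes on chromosome 1 overlap over most of AT1G07887, while the called genes on chromosome 3 share at most 37 exonic bases.

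The other 12 called genes lay apart from one another. PDF1.2 (AT5G44420), a defensin gene induced by jasmonate and ethylene, rose from 0.133 ± 0.0646 to 5.05 ± 2.25 FPKM (limma adjusted p = 0.0249). It has near-identical copies, so its value is uncertain. ESM1 (AT3G14210; chromosome 3, 4729399 to 4731847), a modifier of glucosinolate breakdown, rose from 17.9 ± 0.590 to 39.5 ± 1.62 FPKM (limma adjusted p = 0.0133). The cytochrome P450 gene CYP71B22 rose from 1.23 ± 0.383 to 5.20 ± 0.548 FPKM. AT1G21500, of unknown function, rose from 0.512 ± 0.0170 to 4.27 ± 0.868 FPKM. AT1G55673 rose from 15.69 ± 0.971 to 40.5 ± 6.86 FPKM, but its exons lie wholly within PSAG, a photosystem I gene on the other strand, so it is uncertain. PSAG measured 5.08 ± 0.667 FPKM in WT and 13.6 ± 3.56 FPKM in nid1 and was not called (limma adjusted p = 0.144). The non-coding RNA AT1G08933 was listed at 0 in WT and at 1.54, 1.26 and 1.36 FPKM in nid1. The small nucleolar RNA AT4G39364 fell from 55.9 ± 9.70 to 12.7 ± 1.51 FPKM, the non-coding RNA AT2G01422 from 26.7 ± 6.37 to 4.50 ± 0.973 FPKM, and the pectin lyase-like gene AT5G14650 from 33.2 ± 4.18 to 14.9 ± 0.924 FPKM. AT4G39364 (chromosome 4, 18305415 to 18305536) and AT1G08933 (chromosome 1, 25219756 to 25219954) are shorter than the assumed fragment length of 200 bp. Their FPKM are therefore uncertain. The pectin lyase-like gene AT5G14650 kept its call in 7 of the 14 other settings. It lost it without a filter, after rescaling by median ratios (limma adjusted p = 0.0616, with log2 fold changes of -1.10 as deposited and -1.11 rescaled) and when any 1 library but WT replicate 2 was left out. PDF1.2, CYP71B22 and AT1G55673 also lost their calls without a filter.

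The 5 nitrate uptake and assimilation genes named in advance had lower means in nid1, but none was called. Nitrate reductase gene NIA1 measured 66.7 ± 13.4 FPKM in WT and 40.8 ± 0.718 FPKM in nid1 (limma adjusted p = 0.289), and NIA2 measured 385 ± 33.1 and 258 ± 12.9 FPKM (limma adjusted p = 0.337). The values of the dual-affinity nitrate transporter NRT1.1 were 131 ± 9.04 and 105 ± 1.13 FPKM (limma adjusted p = 0.727). The high-affinity transporter NRT2.1 measured 301 ± 70.4 and 213 ± 24.4 FPKM (limma adjusted p = 0.815), and nitrite reductase NIR1 81.4 ± 16.0 and 67.1 ± 9.06 FPKM (limma adjusted p = 1.00). Of 17 tested genes of nitrogen assimilation, 0 were called by limma over all genes, 3 had an unadjusted p under 0.05 and 2, NIA1 and NIA2, were lower when adjusted over the list alone. The list as a whole was lower (camera adjusted p = 0.0219), with 12 members below 0, a median log2 fold change of -0.14 and an adjusted p of 0.397 with an estimated correlation. Without WT replicate 3 the median was -0.09. Without WT replicate 3, nid1 replicate 1 or nid1 replicate 2 the camera adjusted p was 0.186, 0.103 and 0.0701.

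Regulators and sentinels of the nitrate response were also lower as a list (camera adjusted p = 0.0219; adjusted p = 0.520 with an estimated correlation). None of its 31 tested members passed over all genes or adjusted over the list alone; 2 had an unadjusted p under 0.05 and 20 lay below 0. The median log2 fold change was -0.09 over all libraries, -0.13 without WT replicate 2, -0.01 without WT replicate 3 and -0.03 without nid1 replicate 1. The means of this list overlapped between the genotypes (exact permutation p = 0.5, two-sided), with nid1 replicate 3 above WT replicates 1 and 2. ANR1, a MADS-box factor of root growth in nitrate, measured 20.13 ± 6.09 FPKM in WT and 9.63 ± 2.14 in nid1, and the GATA factor GNC, which acts in chloroplast development, 1.63 ± 0.223 and 2.93 ± 0.395. The camera adjusted p was 0.457 without WT replicate 3, 0.206 without nid1 replicate 1 and 0.0778 without nid1 replicate 2. Nitrate transporters (20 tested, median log2 fold change -0.05, camera adjusted p = 0.0947), other nitrogen transporters (12 tested, median -0.06, adjusted p = 0.374) and CC-type glutaredoxins (7 tested, median -0.16, adjusted p = 0.0947) had no called member and were not called as lists. The median of the other nitrogen transporters was -0.03, with a camera direction upward, without WT replicate 1 and -0.09 without nid1 replicate 3. The median of the glutaredoxins was -0.32 without WT replicate 1 and 0.11 without WT replicate 2 (camera adjusted p = 0.637), whose list mean of 5.23 was the highest of the 6 libraries. Unadjusted p was under 0.05 for 6, 0 and 1 of their members. Nitrate transporters were lower as a list without WT replicate 2 (camera adjusted p = 0.00183, median -0.15) and without nid1 replicate 3 (0.0175, median -0.13), other nitrogen transporters without WT replicate 2 (0.0125) and glutaredoxins without nid1 replicate 1 (0.0232). With all 6 libraries and an estimated correlation the adjusted p of these lists were 0.446, 0.697 and 0.520.

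Photosynthesis genes formed the list with the largest shift. Of 27 tested members 26 were above 0, with a median log2 fold change of 1.13 (camera adjusted p = 1.03e-38; adjusted p = 0.397 with an estimated correlation). Over all genes limma called 0, 24 had an unadjusted p under 0.05 and 24 were higher when adjusted over the list alone. The light-harvesting genes LHCB4.2 and LHCB2.2 measured 11.6 ± 3.51 and 8.49 ± 0.642 FPKM in WT against 45.9 ± 15.2 and 25.8 ± 7.74 FPKM in nid1. LHCA2 measured 33.6 ± 6.03 and 94.6 ± 25.6 FPKM, and the photosystem I gene PSAD1 23.3 ± 3.43 and 51.7 ± 11.99 FPKM. Members of the LHCB and RBCS families have near-identical copies and are uncertain singly. Without nid1 replicate 1 limma called LHCB2.2 (adjusted p = 0.0169), LHCB4.2 (0.0415) and LHCA2 (0.0408) over all genes. List means lay higher in each nid1 library than in each WT library (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows).

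**Figure D3:**
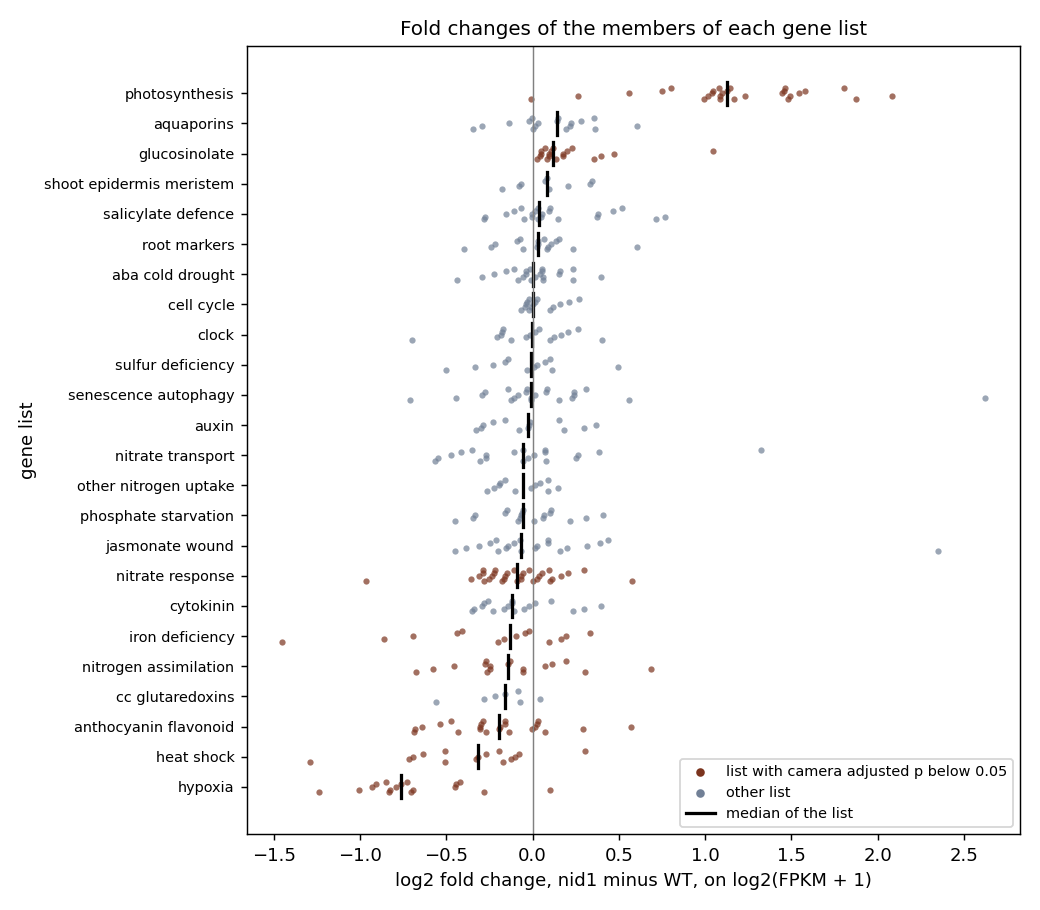
Log2 fold changes of nid1 over WT on log2(FPKM + 1) (horizontal axis) for every tested member of 24 gene lists (rows), with a black bar at each median; brown lists have a camera adjusted p under 0.05 at the preset correlation. Photosynthesis lies highest, at a median of 1.13, and hypoxia lowest, at -0.76.

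Core genes of the hypoxia response were lower as a list, with 16 of 17 members below 0 and a median log2 fold change of -0.76 (camera adjusted p = 9.93e-14; adjusted p = 0.397 with an estimated correlation). Over all genes limma called 0, 11 had an unadjusted p under 0.05 and 4 were lower when adjusted over the list alone. These were lactate dehydrogenase LDH (76.1 ± 3.96 FPKM in WT, 55.8 ± 4.21 in nid1), sucrose synthase SUS4 (146 ± 26.1 and 79.0 ± 25.4), calmodulin-like CML38 (154 ± 58.7 and 73.4 ± 15.3) and pyruvate decarboxylase PDC1 (466 ± 116 and 245 ± 67.3). The list means were 6.49, 7.22 and 6.81 in WT replicates 1, 2 and 3 and 6.49, 6.24 and 5.72 in nid1 replicates 1, 2 and 3. WT replicate 2, which stood apart over all genes, was the highest, and the ranges of the genotypes met at 6.49 (exact permutation p = 0.2, two-sided). The list median was -0.46 without WT replicate 2 and -0.48 without nid1 replicate 3.

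Heat shock genes were lower as a list too (14 of 15 below 0, median -0.32, camera adjusted p = 1.13e-07; adjusted p = 0.397 with an estimated correlation). Of these, limma called 0 over all genes, 6 had an unadjusted p under 0.05 and 5 were lower when adjusted over the list alone. The small heat shock genes HSP23.6 and HSP17.6C measured 3.18 ± 0.484 and 1.96 ± 0.287 FPKM in WT against 0.756 ± 0.509 and 0.800 ± 0.178 FPKM in nid1. The small heat shock genes of the HSP17 group resemble one another closely and are uncertain singly.

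**Figure D4:**
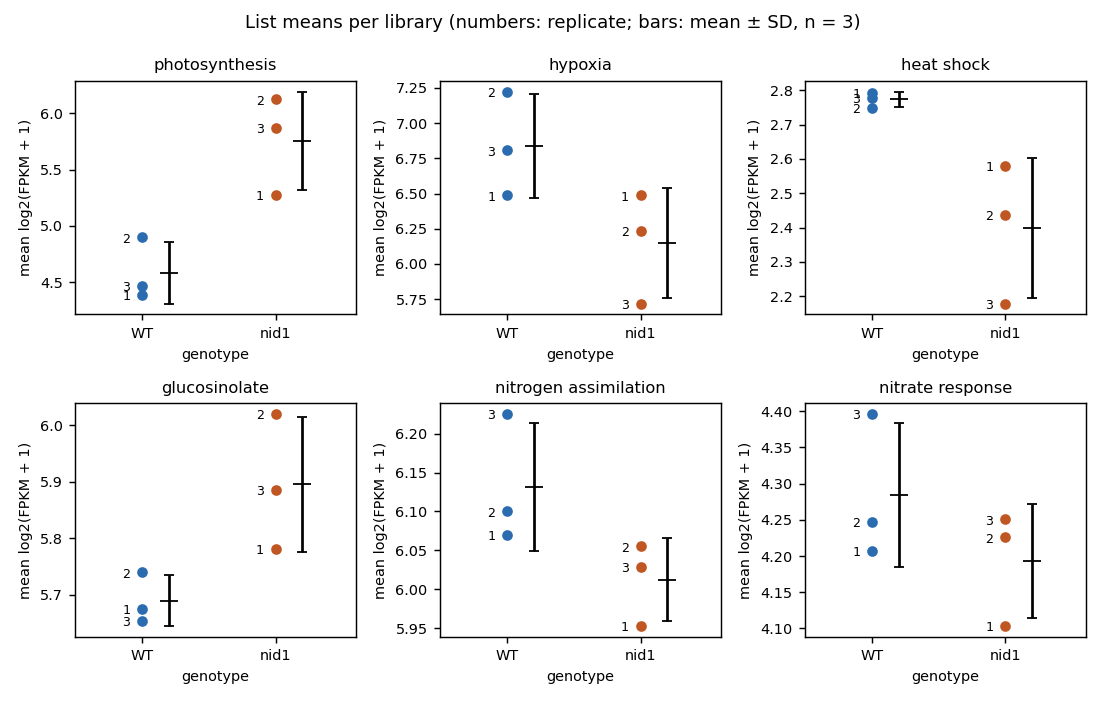
Mean log2(FPKM + 1) over the tested members of 6 lists (vertical axes, which do not start at 0) in each library of WT (blue) and nid1 (orange), with replicate numbers beside the points and bars for mean ± SD (n = 3). Photosynthesis separates the genotypes, while for hypoxia WT replicate 1 and nid1 replicate 1 both lie at 6.49.

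Glucosinolate biosynthesis genes were higher as a list, with all 19 tested members above 0 (median 0.12, camera adjusted p = 0.000184; adjusted p = 0.446 with an estimated correlation). The median was 0.21 without nid1 replicate 1 and 0.05 without nid1 replicate 2. None was called by limma over all genes, 3 had an unadjusted p under 0.05 and 1 was higher when adjusted over the list alone. This was CYP79F1, which acts in the synthesis of aliphatic glucosinolates, at 8.99 ± 1.69 FPKM in WT and 19.5 ± 2.58 FPKM in nid1. Flavonoid and anthocyanin genes were lower (17 of 23 below 0, median -0.19, camera adjusted p = 7.78e-05; adjusted p = 0.446 with an estimated correlation), with 0 called by limma over all genes or adjusted over the list alone and 7 at an unadjusted p under 0.05. Its median was -0.31 without WT replicate 1 and -0.13 without nid1 replicate 3. The list means overlapped (exact permutation p = 0.2, two-sided), with nid1 replicate 2 at 5.62 above WT replicate 1 at 5.55. Chalcone synthase CHS measured 359 ± 84.8 and 219 ± 17.75 FPKM and chalcone isomerase CHI 53.8 ± 7.81 and 34.2 ± 5.60 FPKM. Iron deficiency genes were lower (10 of 14 below 0, median -0.13, camera adjusted p = 0.0219; adjusted p = 0.397 with an estimated correlation). The median was -0.24 without WT replicate 1, -0.06 without WT replicate 2, -0.08 without nid1 replicate 1 and -0.06 over 20 members without a filter. The camera adjusted p was 0.161 without WT replicate 2 and 0.0925 without WT replicate 3. In the iron list limma called 0 over all genes, 4 had an unadjusted p under 0.05 and 1 was lower when adjusted over the list alone, the root iron transporter IRT1 (2.64 ± 0.243 and 0.392 ± 0.531 FPKM). Without nid1 replicate 1 limma called IRT1 over all genes (adjusted p = 0.0169). In both the flavonoid and iron lists WT replicate 2 had the highest mean of the 6 libraries, at 5.93 and 4.03.

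Sulfur deficiency genes were not called as a list (12 tested, median -0.01, camera adjusted p = 0.546), but 2 sulfate transporters passed when adjusted over the list alone. SULTR1;2 was lower in nid1 (10.02 ± 0.730 and 6.78 ± 0.0565 FPKM) and SULTR1;1 higher (2.23 ± 0.429 and 3.52 ± 0.0103 FPKM). PDF1.2 was the only called member of any list, and the jasmonate and wound list (21 tested) had a median of -0.07, a mean of 0.08 and a camera direction downward at an adjusted p of 0.996. Camera adjusted p was 0.760 for senescence and autophagy (22 tested, median -0.01, mean 0.10, direction upward), 0.775 for phosphate starvation (18, median -0.06) and 0.792 for the clock (16, median -0.000569). It was 0.307 for salicylate and defence (22, median 0.04) and 0.996 for abscisic acid, cold and drought (22, median 0.00, direction downward). For cytokinin it was 0.0974 (18, median -0.12), for auxin 0.546 (13, median -0.02), for aquaporins 0.307 (17, median 0.14) and for cell division 0.643 (15, median 0.00). With 1 library left out the cytokinin median ran from -0.19 (nid1 replicate 2) to -0.05 (nid1 replicate 1) and the aquaporin median from -0.03 (WT replicate 3) to 0.15 (nid1 replicate 3). Those of the salicylate list ran from -0.07 (WT replicate 1) to 0.17 (WT replicate 2) and of the auxin list from -0.09 (nid1 replicate 2) to 0.01 (nid1 replicate 1). In the senescence, phosphate, clock, sulfur, jasmonate, abscisic acid, cell division and root marker lists the median was below 0 without at least 1 library and above 0 without another. The phosphate median ran from -0.04 (WT replicate 3) to 6.76e-05 (WT replicate 2). Over all genes limma called 0 members of the 9 lists from senescence to cell division, nor did any pass when adjusted over the list alone. The salicylate list was higher without nid1 replicate 3 (camera adjusted p = 0.0146, median 0.13) and the aquaporins without WT replicate 2 (0.0267, median 0.15). With all 6 libraries and an estimated correlation the adjusted p was 0.859 for both.

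The organ make-up of the samples was followed through marker lists. Root markers were not called as a list (17 tested, median log2 fold change 0.03, camera adjusted p = 0.792), nor were markers of shoot epidermis and meristem (9 tested, median 0.08, camera adjusted p = 0.180), whose median was 0.15 without nid1 replicate 1 and 0.04 without nid1 replicate 2. None of the 9 seed storage genes passed the filter. PYK10, a root beta-glucosidase, ranked 3 in the WT means at 3761 ± 295 FPKM and 3 in the nid1 means at 2848 ± 82.8 FPKM. The Rubisco small subunit gene RBCS1A ranked 1743 in WT, at 97.4 ± 8.91 FPKM, and 602 in nid1, at 213 ± 62.7 FPKM. The light-harvesting gene LHCB1.3 ranked 1490 in WT, at 111 ± 40.9 FPKM, and 351 in nid1, at 306 ± 74.9 FPKM. In light-grown whole seedlings Rubisco and light-harvesting transcripts are usually among the most abundant, unlike the ranks of these genes in either genotype here. Of the 24 lists tested, camera called 8 at the preset correlation, while camera with an estimated correlation called 0 and fry called 0. At an unadjusted p under 0.05 they gave 1 and 3 lists.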

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

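The filter applied again after leaving out a library, and list tests under other pseudocounts, filters, scalings and variance settings, were chosen after seeing the data. All 18 called genes kept their direction in each of the 14 planned settings, and 7 kept their call in all 14. The count stayed between 18 and 20 under both pseudocounts, both filters, rescaling, no trend and robust moderation, although the lack of a filter ended 4 of the original calls and rescaling 1. Leaving out 1 library gave 8 to 35 calls, 4 to 26 higher and 4 to 9 lower. With the filter applied again the counts were 13 (8 higher, 5 lower), 25 (19, 6) and 9 (5, 4) without WT replicates 1, 2 and 3 and 22 (13, 9), 4 (2, 2) and 6 (2, 4) without nid1 replicates 1, 2 and 3. Of those 7, 3 were then called in the smallest set. That filter by construction drops genes expressed only in the 2 nid1 libraries left; otherwise the cause was not tested. With the replicate block 70 genes were called, 55 higher and 15 lower, and all 18 were among them; of the list members named, LHCB2.2, LHCB4.2, LHCA2 and PSAD1 were also called. The numbers were not taken to pair the libraries. The deviations of same-numbered libraries correlated at -0.01, 0.13 and 0.30, and WT replicate 1 correlated best with nid1 replicate 3. Lists called numbered 7 under the block, which ended the nitrogen assimilation call (adjusted p = 0.0571), and 5 to 10 without 1 library. With an estimated correlation 0 lists were called, and with fry 0; the lowest adjusted p were 0.397 and 0.305.

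Directions turned only for lists that were not called. The jasmonate list turned upward at adjusted p = 0.974 and 0.972 with pseudocounts of 0.1 and 0.5, 0.987 after rescaling and 0.846 with fry, and the abscisic acid list at 0.987 after rescaling and 0.945 with fry. Lists that turned when 1 library was left out had these ranges of adjusted p. They were 0.0125 to 0.830 for other nitrogen transporters, 0.166 to 0.836 for senescence, 0.274 to 0.836 for the clock and 0.719 to 0.973 for jasmonate. For salicylate they were 0.0146 to 0.830, for abscisic acid 0.186 to 0.804, for aquaporins 0.0267 to 0.657 and for root markers 0.119 to 0.971. The settings in which a list turned did not call it.

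The count tests, count normalisations and summing of transcripts that had been planned were not run, because the values are FPKM of genes. What depth limits was not tested by expression level; a simulated log2 change of 0.5 was recovered in 0% of genes.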

Other observations

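The 11 gene families in the next paragraph, the SAG12 and metallothionein genes named, and the tests of rescaling, whole shoots, single libraries, handling, exon overlap, chromosome share and splits by called genes, were chosen after the result was seen; the splits by called lists and the placement of neighbours were planned.

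WRKY transcription factors, many of which act in stress and defence, were lower as a family in nid1, with 45 of 58 tested members below 0 (median log2 fold change -0.15, camera adjusted p = 0.000409; adjusted p = 0.685 with an estimated correlation). Peroxidases were lower too, with 39 of 61 below 0 (median -0.16, camera adjusted p = 0.00469; adjusted p = 0.838 with an estimated correlation). WT replicate 2 had the highest mean log2(FPKM + 1) of the 6 libraries in both families, at 4.40 and 5.78. Chloroplast-encoded genes were higher, with 14 of 15 above 0 (median 0.37, camera adjusted p = 0.00578; adjusted p = 0.685 with an estimated correlation). The libraries were made with a poly(A) kit, and how evenly it captured chloroplast transcripts was not checked. The list means of the chloroplast-encoded genes were 1.37, 1.65 and 1.98 in WT replicates 1, 2 and 3. In nid1 replicates 1, 2 and 3 they were 3.03, 2.09 and 2.03. These means include ArthCr091, a 5S ribosomal RNA shorter than the assumed fragment length of 200 bp, so its FPKM is uncertain. It measured 3805.53, 300.674 and 34.441 FPKM in nid1 replicates 1, 2 and 3 and 55.3436 FPKM in WT replicate 3, the highest WT value. The list means of nid1 replicate 2 and WT replicate 3, 2.09 and 1.98, lay close together, while ArthCr091 differed widely between these libraries. These means therefore do not show that the genotypes stay apart without ArthCr091, and means without it were not computed. Of 318 genes annotated as ribosomal proteins 255 were below 0, but the median was -0.08 and the camera adjusted p 0.0600, or 0.0388 after rescaling, against 0.922 with an estimated correlation on the deposited scale. Their means were 6.00, 6.54 and 6.12 in WT replicates 1, 2 and 3 and 6.25, 6.22 and 6.09 in nid1 replicates 1, 2 and 3, so WT replicate 2 was the highest here too. The other 7 families had camera adjusted p between 0.0958 and 0.811.

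SAG12, a protease gene of leaf senescence, measured 5.16 ± 6.02 FPKM in WT and 28.9 ± 13.2 FPKM in nid1 (SD, n = 3 each; limma adjusted p = 0.309). Which genes set WT replicate 2 apart was not tested. Its FPKM total of 964273 was the highest of the 6 libraries. The metallothionein genes examined held 3.05% of that total, against 1.96% and 2.04% in WT replicates 1 and 3. MT2B measured 14350 FPKM there against 7681 and 7672 in WT replicates 1 and 3, and MT1A 8356 against 3233 and 4155.

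The genotypes gave 18 called genes, and the highest count among the other splits of the 6 libraries into groups of 3 was 2; only 1 of the 10 splits, the real one, gave as many. For called lists the real value was 8 and the highest other 9, so 2 of the 10 splits gave as many. With 10 splits a share under 0.05 cannot be reached.

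The photosynthesis list was higher in nid1 at the preset correlation only (adjusted p = 0.397 with an estimated correlation and 0.305 with fry; limma called 0 of 27 members over all genes and 24 had an unadjusted p under 0.05). Library scaling was not tested by rescaling, which gave a list median of 1.13 but moved the median of all genes only from 0.000218 to -0.00140. A larger share of whole shoots in the nid1 samples stays open. The 9 shoot epidermis and meristem markers had a median log2 ratio of 0.135 (SD 0.244 between markers). The photosynthesis genes had 1.15 (SD 0.494 between genes). Whether these markers follow the share of shoots in this material was not checked, so the gap cannot decide. The marker means were 2.187, 2.444 and 2.405 in nid1 replicates 1, 2 and 3 against 2.29, 2.21 and 2.27 in WT. They were lowest in nid1 replicate 1, as the photosynthesis means were within nid1. Against WT the lists parted in that library, whose photosynthesis mean of 5.28 lay above the WT means of 4.39, 4.90 and 4.47. Within WT, replicate 2 had the lowest marker mean and the highest photosynthesis mean. Leaf transcripts were scarce for samples labelled as whole plants (RBCS1A 97.4 ± 8.91 and root PYK10 3761 ± 295 FPKM in WT), so the material may have been mostly root, for which no tissue reference was used here. A larger share of leaf mesophyll, or an effect of the genotype, may lie behind the shift; neither was tested.

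The hypoxia list was lower in nid1 at the preset correlation only (adjusted p = 0.397 with an estimated correlation). The median log2 change, -0.76 over all libraries, was -0.46 without WT replicate 2 (camera adjusted p = 1.43e-07) and -0.48 without nid1 replicate 3. The list means of WT replicate 1 and nid1 replicate 1 were both 6.49, so the part of WT replicate 2 stays open. The list means of the genotypes overlapped (exact permutation p = 0.2, two-sided, where 3 against 3 allows no less than 0.1). Differences in handling between samples and an effect of the genotype cannot be told apart with these libraries, since handling is not recorded.

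The 18 called genes held 4 pairs that followed one another along a chromosome within 5000 bp. None of 10000 random sets of 18 tested genes held more than 2 such pairs. The share with as many pairs is therefore given at its floor of 1e-04, which argues against chance placement. Genes of the chromosome 1 group share exonic bases, so their pairs may not be separate signals. Fragments shared between overlapping genes may account for part of the chromosome 1 group, where the largest exon overlap was 100% of the smaller gene, but hardly for AT3G55910 and AT3G55920, whose largest overlap with any annotated gene was 5.20%. AT3G55900 overlaps AT3G55890 by 56.6%, but AT3G55890 was at 15.2 FPKM in both genotypes. AT3G55900 was listed at 0 in WT and at 2.434, 3.374 and 1.703 FPKM in nid1. An equal spill in all libraries would not give this difference, but a division that differed between libraries stays open. Exact zeros can also be failed estimates, and other sources of the AT3G55900 signal were not tested. Of 14 loci left after merging neighbours 6 lay on chromosome 3, and a share of 0.276 of random sets had as many on one chromosome, which decides nothing; a sequence or chromatin difference at these loci between the nid1 line and Col-0, linked to the mutation or not, remains a hypothesis that these values do not test.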
